A study of Arabidopsis thaliana with 9 samples.

How the data were processed

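RNA was measured on single-colour Affymetrix arrays in whole Arabidopsis thaliana seedlings of the Columbia background, grown for 108 h in the dark on solid medium with 1% sucrose. Of the 9 arrays, 3 held wild type (Col), 3 held homozygous seedlings of bri1-116, a null mutant of the brassinosteroid receptor kinase BRI1, and 3 held a line that overexpresses AtGATA2, a GATA-type transcription factor (AtGATA2ox). Per the labels' protocols, seedlings were frozen in complete darkness, bri1-116 homozygotes were then picked one by one from a segregating population, and cRNA carrying biotin was made from 10 µg of total RNA. The groups were taken from the labels. No label gives a hybridisation date, a scan date or a culture, so p-values measure only the spread between these samples. The AtGATA2ox arrays entered the repository in a separate run of records from the other 6 arrays, and whether they were hybridised together is not stated, so a hybridisation run and the AtGATA2ox genotype cannot be told apart.

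The deposited values are linear intensities, 1 per probe set and array, between 0.1 and 61453.6. Per the submitters' processing notes, MAS5 and GCRMA were used by the authors, with no version and no statement of which made these intensities. Tested on the values, each deposited array was scaled so that the mean intensity of its probe sets without the lowest and highest 2% was 500, while medians differed between arrays. Such scaling fixes 1 mean per array, so a broad change in 1 direction moves the apparent level of the remaining probe sets the other way. The genome build and detection calls are not given in the sources used here, and no coordinates are printed. Values near the lower end carry no statement of whether the transcript was detected.

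The table held 22810 probe sets, of which 64 array controls were left out of the tests and 22746 were tested. The platform's gene annotation paired 13513 probe sets (59.4%) with 1 gene, 503 with several, and did not list 8730, which stay unnamed here. The 1-gene probe sets covered 13355 loci, and 13436 of them matched the RefSeq gene table of assembly TAIR10.1, which was used for names only. AtGATA2 and BRI1 had no named probe set, so their levels were not analysed here and do not check the labels.

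Intensities were used as log2(value + 1), since they proved linear, with no further normalisation. A fold change is therefore on that scale and is not exact for dim probe sets, whose level may be background. One limma fit (version 3.58.1 in R 4.3.3; lmFit and eBayes with an intensity trend) held all 9 arrays, with 6 residual degrees of freedom, and gave 3 comparisons: AtGATA2ox against Col, bri1-116 against Col, and AtGATA2ox against bri1-116. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over the 22746 tested. Precision is limited by the 3 arrays per genotype.

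The tests, the alternatives, 28 gene lists and the rule for named genes were fixed before the data were examined, except how plastid-encoded genes were recognised. The rule took probe sets with 1 locus, adjusted p under 0.05, no overlap of the 3 arrays of each group, and a mean in at least 1 group at or above the median of all values (124.5). It named the 10 largest rises and 10 largest falls of each genotype against Col, the 5 largest each way between the genotypes, and the 5 genes with the largest smaller fold change among those called in both genotypes (higher, lower and opposite). From each list it allowed up to 4 members per comparison, the called ones with the smallest adjusted p first, and any member of the antenna, chlorophyll and light regulator lists. Genes named outside this rule were chosen after their values were seen. Of the 417 list members fixed outside the plastid genome, 58 had a named probe set. A member counts as measured only where it has a named probe set. Lists with at least 3 measured members were tested, 13 in all, 11 lists had 1 or 2 measured members, and 4 had none. A tested list can thus be a small part of the fixed one, as with 3 of 20 antenna genes, all of the LHCB4 type. Another 23 lists were defined by gene symbol after the annotation was read and before any test was run, and some of their members also belong to the fixed lists. The added lists hold only genes that the annotation names by symbol, so they are not whole families. The fixed rule for the plastid list, by locus prefix, matched no probe set of the annotation, so plastid-encoded genes were recognised by chromosome instead, a change made after the annotation was read. Lists were tested with limma's camera at a preset correlation of 0.01 on the brightest probe set of each locus, against all other loci, with Benjamini-Hochberg adjustment over lists and comparisons, separately for fixed and added lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were run as alternatives.

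Other alternatives were quantile normalisation, centring on the median, leaving out the dimmest 40% of probe sets, a pseudocount of 32, eBayes without a trend or with robust settings, only the 6 arrays compared, array weights, the replicate number as a block, each array left out in turn, a difference of at least 2-fold, adjusted p under 0.01, 1 probe set per locus, the mean of a gene's probe sets, and a looser threshold for shared calls. After the data were seen, scaling to the array's hybridisation controls and leaving out bri1-116 replicates 1 and 2 together were added. That scaling and centring on the median move every fold change of a comparison by the same amount. A sign that changes with them does not change a gene's place among the other genes. With 1 array left in a group the SE is larger whatever the other arrays held, so calls can be lost even where fold changes hold. A floor at the 20th percentile was not used, because at most 3 probe sets of an array shared its lowest value. The covariance of the genotypes' fold changes was set beside 50 simulated data sets in which both genotypes equalled Col and shared its arrays. It was also computed, after the data were seen, with different Col arrays for each genotype, 1 for one and 2 for the other.

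The procedure was tested on simulated data, 5 sets of 22746 probe sets with the residual spread of the arrays and 200 changed probe sets per genotype. For AtGATA2ox against Col it found 22.1%, 50.1% and 66.7% of changes of 1, 2 and 3 on the log2 scale, and 6.7% of its calls were false. For bri1-116 against Col it found 26.3%, 57% and 69.4%, with 6.4% of calls false, and for the direct comparison 28.1%, 55.3% and 71.7%, with 5.3% false. In the arrays themselves 28.5% (AtGATA2ox) and 15.1% (bri1-116) of probe sets were called against Col. More changed probe sets loosen the adjusted p threshold, so the simulated shares do not give the detection rate in these data. A list moved on purpose, that of expansins and xyloglucan endotransglucosylase/hydrolases, was found in 5 of 5 sets. Of 175 tests of the other lists 14 had an unadjusted p under 0.05. Among the other lists was the added one of these same families, which shares moved genes, so the 14 may not all be false. Simulated genes varied independently of each other. In the arrays the estimated correlation within fixed lists ran from -0.36 (root) to 0.68 (heat). The simulation therefore does not give the share of false list calls in these data.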

Results

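Transcript levels were measured in dark-grown seedlings of 3 genotypes with 3 arrays each: wild type (Col), bri1-116, which lacks a working brassinosteroid receptor, and AtGATA2ox, which overexpresses the transcription factor AtGATA2. Brassinosteroids are plant steroid hormones that promote cell elongation in the dark. The series sets the genes that respond to AtGATA2 beside those that respond to loss of BRI1, to look for links between the control of development by light and by brassinosteroids. Values in the text are mean intensity ± SD over n = 3 arrays, and log2 fold changes are given ± SE with limma's adjusted p.

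The arrays of a genotype correlated at 0.891 to 0.941 (Pearson r across probe sets, 9 pairs), and arrays of different genotypes at 0.848 to 0.911 (27 pairs). The median intensity was 140 ± 6.6 in Col, 127 ± 6.96 in bri1-116 and 111 ± 10.8 in AtGATA2ox. The ratio of the 3′ to the 5′ actin control, which rises as RNA or cDNA shortens, was 1.91 ± 0.111 in Col, 3.82 ± 1.01 in bri1-116 and 4.8 ± 0.988 in AtGATA2ox, with no overlap between Col and either genotype. The ubiquitin ratio was 1.08 ± 0.0173, 1.61 ± 0.146 and 1.42 ± 0.171 in the same order. The GAPDH ratio was 1.09 ± 0.156, 1.32 ± 0.136 and 1.2 ± 0.108, with ranges that overlapped (0.95 to 1.26 in Col, 1.21 to 1.47 in bri1-116 and 1.11 to 1.32 in AtGATA2ox). The hybridisation controls, RNAs of known amount added before hybridisation, had a mean log2 intensity of 10.4 ± 0.0702 in Col, 10.8 ± 0.202 in bri1-116 and 11.4 ± 0.235 in AtGATA2ox. The probe set for 25S ribosomal RNA read 8762.9 and 3533.8 on bri1-116 replicates 1 and 2, 107.7 on replicate 3, and 143 to 194.2 on the Col arrays. Bacillus control probe sets, which have no target in plants, had means of up to 37.2 in Col, 39.3 in bri1-116 and 61.8 in AtGATA2ox. A fold change against a level in that range is not exact, and the order of the largest changes depends on such levels.

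**Figure D1:**
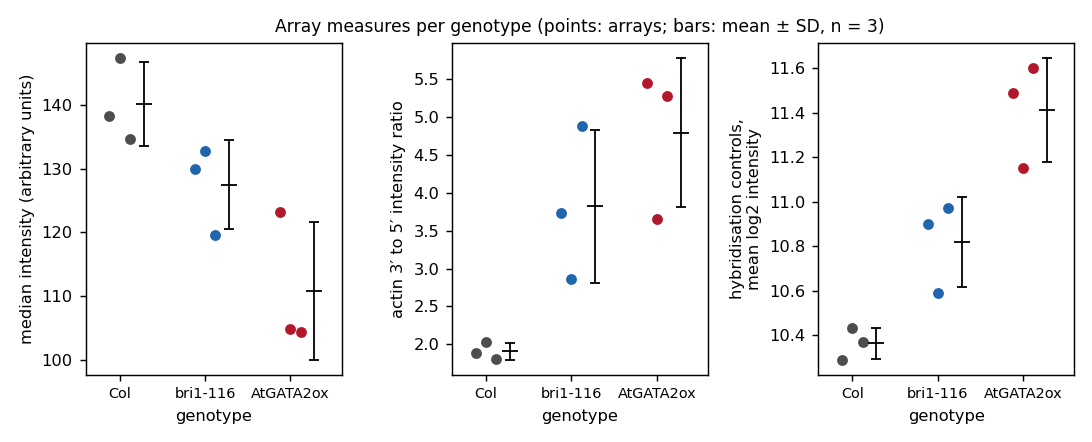
Median intensity, the actin 3′ to 5′ intensity ratio and the mean log2 intensity of the hybridisation controls are plotted for each array (points) with the mean ± SD (bars, n = 3) of Col, bri1-116 and AtGATA2ox. The actin ratio lay between 1.81 and 2.03 in Col, between 2.86 and 4.88 in bri1-116 and between 3.66 and 5.45 in AtGATA2ox.

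The first comparison asked which transcripts differ when AtGATA2 is overexpressed. AT5G62340, of the invertase and pectin methylesterase inhibitor family, was at 16600 ± 1240 in AtGATA2ox against 32.5 ± 20.2 in Col, a level within the range of the Bacillus controls (log2 fold change 9.24 ± 0.49, adjusted p = 7.8e-08). The other 9 of the 10 largest rises included the chitinase family members AT1G56680 (122-fold, 6.93 ± 0.72) and AT2G43620 (61.8-fold, 4430 ± 623 against 75.3 ± 32.4). The thaumatin family member AT1G73620 (77.9-fold, 6.28 ± 0.57) and the calmodulin-like gene AT1G76640 (61.1-fold, 5.93 ± 0.51) rose as well. AT2G28680, of the cupin family, rose 73.5-fold. AT3G60420, AT5G62330, AT3G19920 and AT2G41810 rose by log2 values of 5.92, 5.88, 5.5 and 5.44. The largest falls were of AT4G17470 (92.3-fold, -6.53 ± 0.67, adjusted p = 1.2e-05), and the carnitine transporter gene OCT1 (52-fold, -5.7 ± 0.5). The lipid transfer protein-type gene AT4G22460 (50.4-fold, -5.66 ± 0.59) fell too, as did AT5G10770, of the aspartyl protease family, at 145 ± 17.8 against 6360 ± 1610 (43-fold, -5.43 ± 0.25). The remaining 6 of the 10 largest falls were AT3G26450 (-5.25), AT1G27030 (-4.97, 265 ± 31.8 against 8340 ± 1080), AT1G19900 (-4.89), AT1G11210 (-4.57), AT5G59680 (-4.52) and the copper amine oxidase family member AT1G31710 (-4.44).

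Expansins and xyloglucan endotransglucosylase/hydrolases (XTHs) loosen the cell wall. Of 7 measured members 5 fell in AtGATA2ox, 1 rose and 1 did not pass, with the same counts adjusted over the list alone. The list was called as lower (median -1.46, adjusted p = 0.004, and adjusted p = 0.24 with an estimated correlation). XTH19 fell 18.6-fold (-4.21 ± 0.2, adjusted p = 2.1e-08), EXPA8 fell from 6510 ± 681 to 1620 ± 688 (-2.08 ± 0.24), and EXPA4 and XTH33 fell 2.32-fold and 2.76-fold. The member that rose was EXPA16 (3.31-fold, 1.72 ± 0.3). The wall loosening list lost its call without the dimmest 40% of probe sets (adjusted p = 0.064). All 4 measured nuclear-encoded photosystem subunits rose, also adjusted over the list alone (median 2.13, list adjusted p = 2.7e-07, and adjusted p = 0.089 with an estimated correlation). PSBY rose 5.39-fold (2.43 ± 0.17), PSAE-1 4.85-fold (2.28 ± 0.17), PSAN 3.94-fold (1.98 ± 0.13) and PSBW 2.73-fold (1.45 ± 0.17). Of 3 antenna genes, which encode light-harvesting proteins, LHCB4.1 (1.86 ± 0.2) and LHCB4.2 (1.21 ± 0.18) rose and LHCB4.3 fell (-1.05 ± 0.21). The counts were the same adjusted over the list alone, and the list was not called (adjusted p = 0.19). The starvation list, of genes known to be induced by darkness and lack of sugar, was called as higher (adjusted p = 0.013), but its median of 0.87 became -0.18 with scaling to the hybridisation controls (adjusted p = 0.34). It came to adjusted p = 0.42 with an estimated correlation and lost its call without AtGATA2ox replicate 2 (0.065). Its 4 measured members act in the breakdown of leucine. Of these ETFQO (1.16 ± 0.19), MCCB (1.14 ± 0.24) and IVD (0.6 ± 0.2) rose, also adjusted over the list alone. With scaling to the hybridisation controls none of these was called (0.11, 0.1 and -0.45), nor were EXPA16 (0.68), PSBW (0.4) and LHCB4.2 (0.16).

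The other fixed lists were not called in AtGATA2ox. Of 5 chlorophyll synthesis genes, CHLM (0.93 ± 0.17) and PORB (0.57 ± 0.18) rose. Both genes, and the list's median of 0.38, were below 0 with scaling to the hybridisation controls (-0.11, -0.47 and -0.67). Adjusted over the list alone 2 were higher and 1 lower, and the list had an adjusted p of 0.19 (0.036 without AtGATA2ox replicate 3). In the Calvin cycle list PRK fell (-0.91 ± 0.22), RCA rose (0.65 ± 0.18; -0.4 with scaling to the hybridisation controls) and SBPASE was at -0.45 ± 0.19 (list adjusted p = 0.75; 1 higher and 2 lower adjusted over the list alone). RCA was not called with quantile normalisation, and PRK was not called with centring on the median. Of 69 plastid-encoded genes 12 rose, 5 fell and 52 did not pass, with 11 higher and 5 lower adjusted over the list alone (list adjusted p = 0.27, and 0.022 without AtGATA2ox replicate 3). Subunit genes of photosystem II, psbB (2.7-fold) and psbZ (2.88-fold), were among those that rose, and ndhA, psaA, psbE, atpB and ycf4 fell. The rises of psbB (0.38) and psbZ (0.48) were not called with scaling to the hybridisation controls, nor the falls of psbE, atpB and ycf4 with centring on the median. That list's median was 0, its mean was -0.06, and the test against other genes pointed up, with a median of -0.13 over all loci. The test weighs each gene's change by its spread, so its direction need not follow the medians. The balance depended on the scaling, with 6 higher and 8 lower with quantile normalisation (median -0.11), 21 and 2 with centring on the median (0.34), and 0 and 44 with scaling to the hybridisation controls (-1.05). GH3.3, which encodes an enzyme that conjugates auxin, rose 4.07-fold (2.03 ± 0.25), the only call among 3 auxin genes, also adjusted over the list alone (list adjusted p = 0.4). The small heat shock protein gene AT1G53540 (2.56 ± 0.63) and HSA32 (1.18 ± 0.3) rose among 3 heat genes, also adjusted over the list alone (list adjusted p = 0.1, and 0.024 without AtGATA2ox replicate 1). With scaling to the hybridisation controls the heat list had a median of 0.13 and neither was called. AUR1, an Aurora kinase gene, fell among 3 cell division genes (-1.02 ± 0.27; list adjusted p = 0.48), and the root hair expansin EXPA18 fell among 3 root genes (-2.59 ± 0.75; list adjusted p = 0.64), each also adjusted over the list alone. With quantile normalisation or centring on the median AUR1 was not called. None of 3 stomatal lineage genes and none of 3 reference genes was called, over all probe sets or adjusted over the list alone (list adjusted p = 0.69 and 0.96). With fry the antenna (0.0027), auxin (0.036) and root (0.0098) lists passed.

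**Figure D2:**
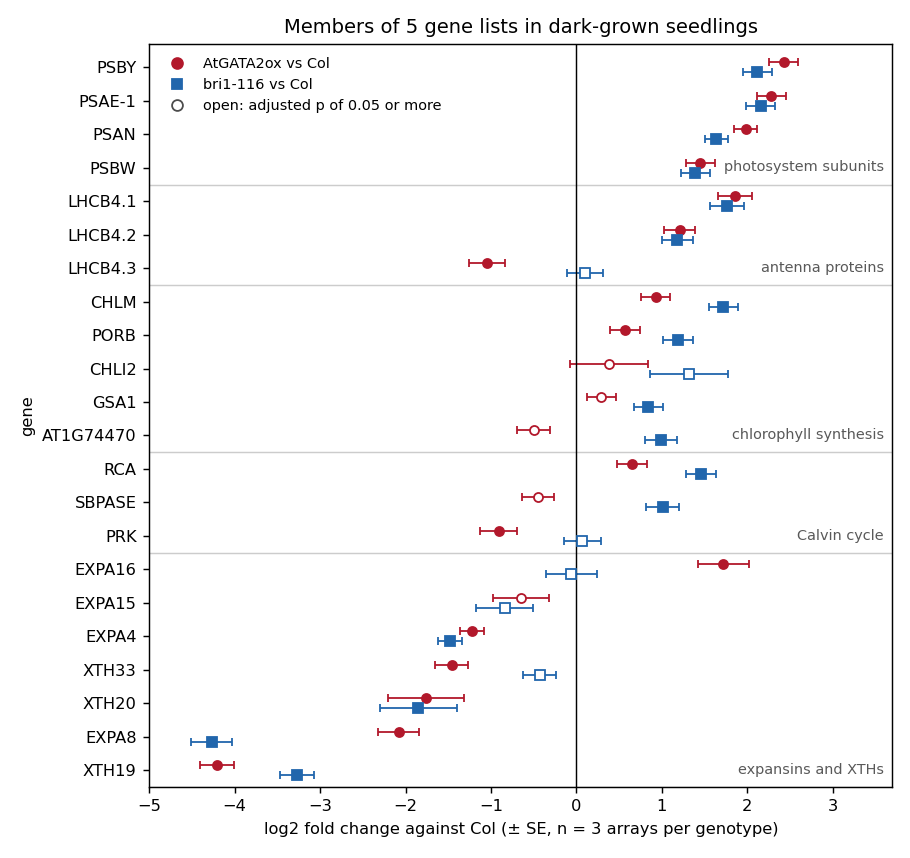
The log2 fold change against Col is plotted for the measured members of 5 fixed gene lists in AtGATA2ox (red circles) and bri1-116 (blue squares), ± SE with n = 3 arrays per genotype, and open symbols mark an adjusted p of 0.05 or more. The 4 photosystem subunits lay between 1.39 and 2.43 in both genotypes, and XTH19 lay at -4.21 in AtGATA2ox and -3.27 in bri1-116.

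Among the lists added later, the defence, calcium and jasmonate list was called as higher in AtGATA2ox, with 9 of 24 members higher and none lower. It had an adjusted p of 0.00059, and adjusted p = 0.28 with an estimated correlation. The list's median of 0.79 became -0.26 with scaling to the hybridisation controls, which moved every fold change of this comparison by -1.05. The zinc finger gene STZ rose 8.15-fold, from 380 ± 206 to 2690 ± 150, the calmodulin-like gene CML37 rose by 4.56 ± 0.99 on the log2 scale and the transcription factor gene WRKY6 rose 5.03-fold (2.33 ± 0.39). Tubulin genes, which encode the subunits of microtubules, were called as lower, with 6 of 7 lower and 1 higher (median -0.96, adjusted p = 0.01, and adjusted p = 0.38 with an estimated correlation). Without the dimmest 40% of probe sets the tubulin list had an adjusted p of 0.12. TUB5 fell 5.08-fold, and the rise of TUA6 (0.66) was -0.39 with scaling to the hybridisation controls. With centring on the median 4 tubulin genes were lower, as TUB6 (-0.14) and TUB9 (-0.49) lost their calls. Of 16 mitochondrion-encoded genes 7 were higher and 1 lower, with a median of 0.5, and of -0.55 with scaling to the hybridisation controls. The mitochondrial list had an adjusted p of 0.0063, and adjusted p = 0.28 with an estimated correlation, and lost its call with scaling to the hybridisation controls (0.18). Its member cox2 rose 4.78-fold and nad5 2.3-fold, the latter at 0.16 and not called with that scaling. Plastid-encoded photosynthesis genes were 8 higher and 3 lower of 33, with a median of 0.32 that was -0.72 with scaling to the hybridisation controls (adjusted p = 0.031, and adjusted p = 0.8 with an estimated correlation). That call was lost with quantile normalisation (0.92), with scaling to the hybridisation controls (0.86), with fry (0.31) and without Col replicate 2 (0.11) or AtGATA2ox replicate 2 (0.32). Of 33 nuclear photosynthesis and thylakoid genes 11 rose and 8 fell, with a median of -0.11, a mean of 0.18 and a test that pointed up (adjusted p = 0.16, and 0.026 with fry). The balance of these genes depended on the scaling too, with 11 higher and 3 lower with quantile normalisation (median 0.31), 12 and 1 with centring on the median (0.23), and 5 and 21 with scaling to the hybridisation controls (-1.16). The calcium-sensing thylakoid protein gene CaS rose 4.54-fold (2.18 ± 0.22), while the adenine nucleotide carrier gene TAAC fell 2.48-fold, but was not called with quantile normalisation (-0.99) or centring on the median (-0.97). Of 13 tetrapyrrole synthesis genes 5 rose and 2 fell, with a median of 0.29 that was -0.76 with scaling to the hybridisation controls, and a mean of -0.13 (adjusted p = 0.28). HEMB1 rose 2.47-fold, and hemf2 (-3.57 ± 0.67) and HEMA2 (-0.86) fell. HEMB1 was at 0.25 and not called with scaling to the hybridisation controls, and HEMA2 was not called with quantile normalisation (-0.46) or centring on the median (-0.52). Of the 28 expansin, expansin-like and XTH genes named by symbol 3 rose and 11 fell (adjusted p = 0.088, and 0.028 without AtGATA2ox replicate 3, 0.031 with quantile normalisation and 0.0063 with fry). The expansin and XTH median was -0.3, and 0.04 with centring on the median. Of the rises that of EXPA9 (0.46) was lost with quantile normalisation (0.12) and became a called fall with scaling to the hybridisation controls (-0.59, adjusted p = 0.028). With that scaling the counts of higher and lower members were 1 and 18 for the expansin and XTH families, 4 and 3 for the defence, calcium and jasmonate list, 1 and 5 for the mitochondrial list, 0 and 16 for plastid-encoded photosynthesis genes and 0 and 5 for tetrapyrrole genes. Plastid-encoded photosynthesis genes were 6 and 7 with quantile normalisation and 16 and 1 with centring on the median.

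In all, 2211 probe sets were higher and 4275 lower in AtGATA2ox than in Col, 28.5% of those tested, and 1269 and 2995 of these differed by at least 2-fold. The 3 arrays of each group did not overlap for 9398 probe sets (41.3%), where chance gives 10%. The share of calls that were higher was 34.1%, and it was 47.2% with quantile normalisation (2685 higher and 2998 lower), 58.1% with centring on the median (3465 and 2501) and 3.4% with scaling to the hybridisation controls (421 and 11909). These scalings moved the median log2 fold change of all probe sets, -0.17, by 0.18, 0.34 and -1.05, so each direction is relative to the scaling used.

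The second comparison asked which transcripts depend on BRI1. AT3G05730, a defensin-like gene, was 55.2-fold higher in bri1-116 than in Col, at 5310 ± 503 against 106 ± 54.9 (5.79 ± 0.47, adjusted p = 3.8e-06). The glutaredoxin family members AT4G15690 (45.7-fold, 5.52 ± 0.53), AT4G15680 (15.4-fold, 3.95 ± 0.5) and AT4G15700 (9.3-fold, 3.22 ± 0.36) rose. So did AT1G22690, of the gibberellin-regulated GASA family (16.7-fold, 4.06 ± 0.29), and AT1G62500, of the lipid transfer protein type (13.8-fold, 1300 ± 241 against 92.1 ± 3.56). AT1G23130 (4.87), the efflux carrier gene AT5G52050 (3.63 ± 0.73, adjusted p = 0.0038), AT5G48490 (3.52) and AT1G21500 (3.46) made up the 10 largest rises. AT5G04120 fell to 30.7 ± 37.3, within the range of the Bacillus controls, from 3420 ± 1740 (-7.38 ± 0.73, adjusted p = 1.7e-05). AT1G72290, of the Kunitz-type protease inhibitor family, fell 62.9-fold (-5.98 ± 0.9). The expansin gene EXPA8 fell 19.4-fold, to 339 ± 65.2 from 6510 ± 681 (-4.27 ± 0.24, adjusted p = 3.3e-07). The other large falls were of AT4G17470 (-5.57), AT1G70270 (-5.09), AT1G19900 (-4.92), the UDP-glycosyltransferase family member AT2G22930 (-4.75), AT4G22460 (-4.13), AT4G15830 (-4.01) and AT2G34700 (-3.81). AT4G15830 had an adjusted p of 0.022 and lost its call without bri1-116 replicate 1 or 3 (0.096 for both) and without Col replicate 1, 2 or 3 (0.075, 0.07 and 0.061), and with eBayes without a trend (0.086). With replicate 3 as the only bri1-116 array, the log2 fold change was 3.4 for AT5G52050 and -4.54 for AT2G22930.

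Of the 7 wall loosening genes 4 fell in bri1-116 and none rose, with 5 lower adjusted over the list alone (median -1.48, list adjusted p = 6.5e-07, and adjusted p = 0.089 with an estimated correlation). Those that fell were EXPA8, XTH19 (9.61-fold, -3.27 ± 0.2), EXPA4 (2.79-fold, -1.48 ± 0.14) and XTH20 (-1.85). All 4 photosystem subunits rose, also adjusted over the list alone (median 1.88, list adjusted p = 3e-08, and adjusted p = 0.089 with an estimated correlation). PSAE-1 rose 4.46-fold, PSBY 4.36-fold (2.12 ± 0.17) and PSAN 3.11-fold (1.64 ± 0.13). Of the antenna genes LHCB4.1 (3.38-fold, 18100 ± 2620 against 5420 ± 1190) and LHCB4.2 (2.26-fold) rose, also adjusted over the list alone. LHCB4.3 was at 0.1 ± 0.21 (list adjusted p = 0.011, and adjusted p = 0.2 with an estimated correlation). Of 5 chlorophyll synthesis genes 4 rose, and all 5 adjusted over the list alone (median 1.19, list adjusted p = 1.6e-05, and adjusted p = 0.24 with an estimated correlation). Among them CHLM, a methyltransferase gene, rose 3.3-fold (1.72 ± 0.17) and PORB, a protochlorophyllide oxidoreductase gene, 2.28-fold (1.19 ± 0.18). In the Calvin cycle list RCA, the Rubisco activase gene, rose 2.75-fold and SBPASE 2.02-fold, also adjusted over the list alone, and PRK was at 0.07 ± 0.22. The list had an adjusted p of 0.014, and adjusted p = 0.32 with an estimated correlation. In the auxin list WES1, an auxin-conjugating enzyme gene, rose 2.41-fold and IAA29 2.22-fold, also adjusted over the list alone, and GH3.3 was at -0.07 ± 0.25. The list had an adjusted p of 0.034, and adjusted p = 0.24 with an estimated correlation. The Calvin cycle call was lost without bri1-116 replicate 3 (adjusted p = 0.067), without the dimmest 40% of probe sets (0.073) and with scaling to the hybridisation controls (0.063). The auxin call was lost without bri1-116 replicate 2 (0.055), bri1-116 replicate 3 (0.067) or Col replicate 1 (0.081). It was also lost without the dim probe sets (0.11), with scaling to those controls (0.067) and with eBayes without a trend (0.082). SBPASE (0.56) and IAA29 (0.7) were not called with that scaling.

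Of 69 plastid-encoded genes 4 were higher in bri1-116 and 65 did not pass, with 1 higher adjusted over the list alone (list adjusted p = 0.17, and 0.038 with array weights). The smallest adjusted p among them was that of psbB (0.75 ± 0.14, 0.0028; 0.29 and not called with scaling to the hybridisation controls). The list's median of 0.17 was -0.28 with scaling to the hybridisation controls. In this list bri1-116 replicates 1 and 2, bright for 25S ribosomal RNA, differed from replicate 3. Without bri1-116 replicate 3 the list's median was 0.349 (adjusted p = 4.2e-05), and with replicate 3 as the only bri1-116 array it was -0.294. Replicate 3 also had the highest actin 3′ to 5′ ratio of its group, 4.88 against 3.73 and 2.86. Its median intensity was the lowest, 119.6 against 130 and 132.8. These differences separate the same arrays and cannot be told apart. AUR1 fell among the cell division genes (-1.35 ± 0.27), with 2 lower adjusted over the list alone (list adjusted p = 0.057). That list passed with centring on the median (0.041) and without bri1-116 replicate 1 (0.034), Col replicate 3 (0.028), AtGATA2ox replicate 1 (0.047) or AtGATA2ox replicate 2 (0.049), and with fry (0.04). No member of the heat, starvation, stomatal lineage, root or reference lists was called, over all probe sets or adjusted over the list alone (list adjusted p = 0.71, 0.85, 0.68, 0.7 and 0.68).

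Among the lists added later, 21 of 33 nuclear photosynthesis and thylakoid genes were higher in bri1-116 and none lower (median 0.93, adjusted p = 3.5e-16, and adjusted p = 0.15 with an estimated correlation). CaS was 6.61-fold higher, at 1600 ± 267 against 247 ± 71.7. Of 13 tetrapyrrole synthesis genes 8 were higher (median 1.01, adjusted p = 3e-05, and adjusted p = 0.28 with an estimated correlation), including HEMB1 (2.55-fold) and HEME1 (3.03-fold). Of the 28 named expansin and XTH genes 10 were lower and 2 higher (median -0.48, adjusted p = 4.2e-05, and adjusted p = 0.28 with an estimated correlation). EXPB1 was 4.01-fold and EXPB3 2.95-fold lower. Tubulin genes were 5 lower and 1 higher of 7 (median -0.72, adjusted p = 0.0011, and adjusted p = 0.28 with an estimated correlation). TUB1 was 4.16-fold lower, and the rise of TUB6 (0.42) was -0.04 with scaling to the hybridisation controls. Of 7 histone genes HTB4 (-0.86) and HTB11 (-0.47) were lower (median -0.47, adjusted p = 0.011, and adjusted p = 0.28 with an estimated correlation). The histone call was lost without the dim probe sets (0.072), and the list's median was -0.308 with replicate 3 as the only bri1-116 array. HTB11 was not called with quantile normalisation (-0.43) or centring on the median (-0.33). The defence, calcium and jasmonate list had 1 gene higher and 1 lower of 24 (adjusted p = 0.85), and mitochondrion-encoded genes 1 higher of 16 (0.44). Plastid-encoded photosynthesis genes were 4 higher of 33 (0.088, and 6.3e-05 without bri1-116 replicate 3, 0.023 without Col replicate 3 and 0.03 with array weights), and none of the 4 was called with scaling to the hybridisation controls. With that scaling the counts of higher and lower members were 13 and 1 for nuclear photosynthesis, 4 and 1 for tetrapyrrole synthesis, 2 and 14 for expansins and XTHs, 0 and 6 for tubulins and 0 and 4 for histones, and 2 of the 5 chlorophyll synthesis genes were higher. With centring on the median 8 expansins and XTHs and 4 tubulins were lower.

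In all, 1612 probe sets were higher and 1819 lower in bri1-116 than in Col, 15.1% of those tested, and 814 and 1181 of these differed by at least 2-fold. Without Col replicate 2 the counts were 1055 and 1097, and with replicate 3 as the only bri1-116 array 571 and 845. The bri1-116 counts were 1900 and 2215 without AtGATA2ox replicate 2. Fits of only the 6 arrays compared called 5182 probe sets for bri1-116 against Col and 5507 for AtGATA2ox against Col. The gap between the shares called, 28.5% for AtGATA2ox and 15.1% for bri1-116, thus depended on fitting all 9 arrays together. The groups did not overlap for 8542 probe sets (37.6%), where chance gives 10%. The share of calls that were higher was 47%, and it was 51.2% with quantile normalisation (1860 higher and 1772 lower), 59.9% with centring on the median (1986 and 1329) and 12.5% with scaling to the hybridisation controls (482 and 3381).

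The last comparison set AtGATA2ox directly against bri1-116. AT5G62340 (200-fold), AT1G76640 (198-fold, 7.63 ± 0.51), AT5G04120 (2260 ± 1120 against 30.7 ± 37.3), AT1G56680 (105-fold) and AT5G62330 (92.3-fold) were the 5 furthest above bri1-116. OCT1 was lower, at 8.43 ± 4.42 against 1020 ± 136 (-6.87 ± 0.5, adjusted p = 9.9e-07), followed by the lipid transfer protein-type gene AT3G53980 (49.2-fold, -5.62 ± 0.44), AT1G11210 (36.3-fold), AT2G37870 (23.5-fold) and AT5G23330 (20.7-fold). All 3 Calvin cycle genes were lower in AtGATA2ox than in bri1-116, also adjusted over the list alone: SBPASE 2.76-fold, PRK 1.98-fold and RCA 1.75-fold. The list had a median of -0.98, an adjusted p of 0.014, and adjusted p = 0.32 with an estimated correlation. Of 5 chlorophyll synthesis genes 4 were lower, also adjusted over the list alone (median -0.79, adjusted p = 0.016, and adjusted p = 0.48 with an estimated correlation). AT1G74470, which encodes geranylgeranyl reductase, was 2.8-fold lower. Starvation genes were 3 higher of 4, also adjusted over the list alone (median 0.87, adjusted p = 0.0099, and adjusted p = 0.42 with an estimated correlation), and ETFQO was 2.49-fold higher. Without the dimmest 40% of probe sets the Calvin cycle and chlorophyll calls were lost (adjusted p = 0.11 for both), and RCA was not called with centring on the median (-0.6). The starvation call was lost with scaling to the hybridisation controls (0.063), and the list's median was 0.707 with replicate 3 as the only bri1-116 array.

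Among the other fixed lists, the 4 photosystem subunits showed no call between the genotypes, over all probe sets or adjusted over the list alone (median 0.21, list adjusted p = 0.27). Of 3 antenna genes LHCB4.3 was lower (-1.15 ± 0.21), and the list's median of 0.03 went with a test that pointed down (0.69). The wall loosening genes were 2 higher and 2 lower of 7 (0.41): EXPA8 4.57-fold and EXPA16 3.45-fold higher, XTH33 2.05-fold and XTH19 1.93-fold lower in AtGATA2ox. The wall loosening median of 0.19 was -0.41 with scaling to the hybridisation controls. In the auxin list GH3.3 was 4.27-fold higher and WES1 3.01-fold and IAA29 2.02-fold lower (0.69). Plastid-encoded genes were 5 higher and 7 lower of 69, and 4 and 5 adjusted over the list alone, with a median of -0.16 and a test that pointed up (0.85, and 0.00043 with replicate 3 as the only bri1-116 array). They were 4 higher and 9 lower with quantile normalisation, 7 and 3 with centring on the median (median 0.05), and 0 and 23 with scaling to the hybridisation controls (-0.75). AT1G53540 was 9.73-fold higher in the heat list (0.21). The reference list had 1 lower of 3, AT2G28390 (0.7), which was not called with quantile normalisation or centring on the median, and the cell division, stomatal lineage and root lists had no call (0.43, 0.96 and 0.75). The stomatal median, also -0.16, went with a test that pointed up as well. Counts adjusted over the list alone equalled those over all probe sets in the antenna, wall loosening, auxin, heat, reference, cell division, stomatal and root lists. Among the lists added later, 19 of 33 nuclear photosynthesis genes were lower in AtGATA2ox and none higher (median -0.91, adjusted p = 3.2e-05, and adjusted p = 0.28 with an estimated correlation). TROL was 4.99-fold and the ascorbate peroxidase gene TAPX 3.28-fold lower. Tetrapyrrole synthesis genes were 7 lower of 13 (median -0.62, adjusted p = 0.016, and adjusted p = 0.67 with an estimated correlation). Their call was lost without AtGATA2ox replicate 3 (0.067) and without the dim probe sets (0.092). Defence, calcium and jasmonate genes were 8 higher of 24 (median 0.83, adjusted p = 0.00041, and adjusted p = 0.28 with an estimated correlation), STZ 11.7-fold. The other lists described against Col were not called: expansins and XTHs were 5 higher and 4 lower (0.23), tubulin genes 2 and 2 (0.91), histone genes 3 and 2 (0.49), mitochondrion-encoded genes 3 and 1 (0.071), and plastid-encoded photosynthesis genes 5 and 3 (0.4). The higher and lower members with scaling to the hybridisation controls were 2 and 7 for expansins and XTHs, 0 and 5 for tubulins, 0 and 2 for histones, 1 and 3 for mitochondrion-encoded genes, and 0 and 11 for plastid-encoded photosynthesis genes. Nuclear photosynthesis genes were 0 and 27 with that scaling, tetrapyrrole synthesis genes 0 and 11, and defence, calcium and jasmonate genes 6 and 2. With centring on the median 4 tetrapyrrole and 2 chlorophyll synthesis genes were lower. The antenna (0.049), auxin (0.024) and root (0.028) lists passed with fry. The mitochondrial list passed with quantile normalisation (0.037), without the dim probe sets (0.045), with the mean of a gene's probe sets (0.04) and with fry (0.0082). The plastid-encoded photosynthesis list passed with replicate 3 as the only bri1-116 array (median 0.518, adjusted p = 0.00023).

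In all, 2172 probe sets were higher and 3914 lower in AtGATA2ox than in bri1-116, 26.8% of those tested, and 1416 and 2553 of these differed by at least 2-fold. The groups did not overlap for 8546 probe sets (37.6%), where chance gives 10%. The share of calls that were higher was 35.7%, and it was 45.2% with quantile normalisation (2519 higher and 3050 lower), 50% with centring on the median (2722 and 2717) and 10.5% with scaling to the hybridisation controls (912 and 7754). With replicate 3 as the only bri1-116 array the counts were 1071 and 1207.

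The series also asks which genes respond in both genotypes. Called higher than in Col in both were the glutaredoxin family members AT4G15690 (5.34 ± 0.53 in AtGATA2ox and 5.52 ± 0.53 in bri1-116) and AT4G15680 (3.9 ± 0.5 and 3.95 ± 0.5), and AT1G23130 (4.27 and 4.87), AT5G52050 (5.38 and 3.63) and AT1G21500 (3.18 and 3.46). Called lower in both were AT4G17470 (-6.53 and -5.57), AT1G19900, of the glyoxal oxidase family (-4.89 and -4.92), AT4G22460 (-5.66 and -4.13), AT2G22930 (-3.86 and -4.75) and AT1G30760, of the berberine bridge enzyme family (-3.9 and -3.65). Called in opposite directions were AT3G53980 (-3.58 and 2.04), AT4G32870 (2.42 and -1.97), AT2G21850 (1.78 and -1.75), the asparaginase gene ASPGB1 (1.82 and -1.8) and AT5G52750, of a heavy metal-binding family (2.44 and -2.14). Without AtGATA2ox replicate 3 the fall of AT2G22930 in AtGATA2ox lost its call (adjusted p = 0.054). The bri1-116 call of ASPGB1 was lost without bri1-116 replicate 1 (0.093) or Col replicate 2 or 3 (0.057 and 0.083), and that of AT5G52750 without bri1-116 replicate 1, 2 or 3 (0.088, 0.082 and 0.072) or Col replicate 2 or 3 (0.093 and 0.15). With replicate 3 as the only bri1-116 array the bri1-116 log2 fold changes were 1.79 for AT3G53980, -1.44 for ASPGB1 and -1.98 for AT5G52750. With eBayes without a trend ASPGB1 lost both its calls (0.06 in AtGATA2ox and 0.1 in bri1-116), and AT3G53980 (0.068) and AT5G52750 (0.12) lost theirs in bri1-116. The bri1-116 call of AT5G52750 was also lost with centring on the median (0.051) and a pseudocount of 32 (0.059). With scaling to the hybridisation controls the AtGATA2ox calls of AT2G21850 (0.13), ASPGB1 (0.18) and AT5G52750 (0.068) were lost.

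Both genotypes were called higher for 643 probe sets and lower for 1058, and in opposite directions for 344, of which 160 were higher and 184 lower in AtGATA2ox. Independent lists of these sizes would share 156.7, 341.9 and 479.8. The 2 lists are not independent, because both comparisons use the same Col arrays. That raises sharing in 1 direction and lowers opposite calls without any effect, so these numbers cannot show a shared response. The balance of higher and lower shared calls turned with the scaling, with 990 higher and 659 lower with centring on the median and 93 and 2797 with scaling to the hybridisation controls (809 and 960 with quantile normalisation). Of the 2045 probe sets called in both, 1701 (83.2%) went in the same direction. The 2045 were 31.5% of the AtGATA2ox calls and 59.6% of the bri1-116 calls. The 344 opposite calls were all called in the direct comparison too. The shared fit makes this so, because their direct difference is larger with the same SE, and it is no separate evidence. The log2 fold changes of the genotypes had a covariance of 0.455 across probe sets, against 0.209 on average in 50 simulated sets with no effect but the same Col arrays, a difference of 0.246. Pearson r was 0.43 against 0.5, and 63.4% against 66.7% had the same sign. With 1 Col array for one genotype and the other 2 for the other, the covariance was 0.246 to 0.344 over the 6 ways, r was 0.193 to 0.279, and 56.9% to 59.5% had the same sign. The shared calls themselves were not counted with different Col arrays. Without Col replicate 2 the shared counts were 416 higher, 626 lower and 162 opposite, and the opposite count was also 200 and 204 without bri1-116 replicates 1 and 2 and 206 and 171 without Col replicates 1 and 3.

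**Figure D3:**
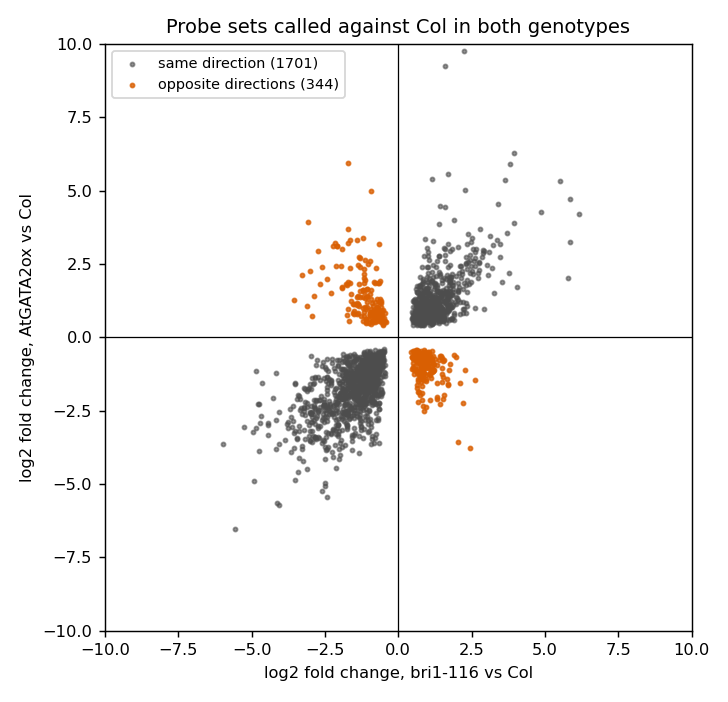
Each point is a probe set called in both genotypes, with its log2 fold change against Col in bri1-116 (horizontal axis) and in AtGATA2ox (vertical axis). The 1701 probe sets called in the same direction are grey and the 344 called in opposite directions orange.

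Of the fixed lists with 1 or 2 measured members, COR47, a cold-induced dehydrin gene, fell in both genotypes, 12-fold in AtGATA2ox (336 ± 39.3 against 4050 ± 507, adjusted p = 1.8e-08) and 3.96-fold in bri1-116 (-1.99 ± 0.16), with COR15A at -1.81 ± 0.82 and -1.04 ± 0.82. The gibberellin receptor gene GID1B rose in AtGATA2ox (1.2 ± 0.25) and fell in bri1-116 (-0.8 ± 0.25), and GID1A rose in bri1-116 (0.72 ± 0.18) and was at -0.13 ± 0.18 in AtGATA2ox. With scaling to the hybridisation controls neither of these rises was called, and the fall of GID1B was not called with centring on the median. EIN3, of ethylene signalling, fell in both (-0.78 ± 0.18 and -0.57 ± 0.18), but was called in neither with quantile normalisation (-0.51 and -0.53) or centring on the median (-0.44 and -0.44). GUT2, of secondary wall xylan synthesis, fell in AtGATA2ox (-1.43 ± 0.28) and was at -0.31 ± 0.28 in bri1-116, and COB, of primary wall cellulose deposition, fell in bri1-116 (-0.44 ± 0.13; -0.3 and not called with centring on the median) and was at -0.05 ± 0.13 in AtGATA2ox. The clock gene GI fell in AtGATA2ox (-0.96 ± 0.17) and was at -0.49 ± 0.17 in bri1-116, and the seed gene PAP85 rose in AtGATA2ox (2.29 ± 0.51; 1.24 and not called with scaling to the hybridisation controls). HYH, a light-response transcription factor gene, was at 2.45 ± 0.99 in AtGATA2ox (adjusted p = 0.085), and DFR, UF3GT, PDF1.2 and YAB3 were not called against Col in either genotype (0.99, -0.23, -0.11 and -0.02 in AtGATA2ox). These lists were too small to be tested as lists. No member of the brassinosteroid metabolism, brassinosteroid signalling, jasmonate or cuticle lists had a named probe set.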

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

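Among the tests in this part, that of 3′ bias was chosen before its result was seen, and the others, with the scaling to the hybridisation controls, were chosen after theirs were seen.

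Among the array control probe sets, which the comparisons do not use, 2 had a lowest AtGATA2ox array at least 2 times the highest Col array. The control probe set for U12639 had a mean intensity of 3240 ± 669 in AtGATA2ox, against 31.2 ± 25.8 in Col and 48 ± 9.06 in bri1-116 (n = 3 each). A control for bioC, 1 of the bacterial transcripts added at hybridisation, had 1860 ± 240 in AtGATA2ox, against 767 ± 21.1 in Col and 1180 ± 147 in bri1-116, and its lowest AtGATA2ox array (1634.9) was above the highest Col array (790.9). It was not alone, since the lowest AtGATA2ox array was above the highest Col array for every bioB, bioC, bioD and cre control, with log2 differences of 0.85 to 1.27. The same held for the 5S ribosomal RNA probe set (56.5 against 31.4) and for some actin, GAPDH and ubiquitin controls.

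A higher background on the AtGATA2ox arrays would lift controls that have no target in plants, and the 27 Bacillus control probe sets differed by a median log2 of 0.76 between AtGATA2ox and Col (-1.45 to 2.06), which argues against background as the cause of the U12639 signal. Sequence brought in with the AtGATA2 construct may be the source of the difference, in which the dimmest AtGATA2ox array was 42.7 times the brightest of the other 6 (2473.3 against 57.9). It stays open, because neither the probe sequences nor the construct sequence were used here. A hybridisation run that differs for the AtGATA2ox arrays cannot be told apart from the genotype either.

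The larger number of probe sets lower than higher in AtGATA2ox depended on how the arrays were scaled. Of the calls, 34.1% were higher as reported, 47.2% with quantile normalisation and 3.4% with scaling to the hybridisation controls, so the scaling of each array to 1 trimmed mean may account for the imbalance or may hide part of a larger one. The tests moved it both ways, and the share of messenger RNA in the labelled RNA was not measured, which keeps both open. Loss of dim probe sets on arrays with less labelled target stays open too. The share was 33.7% without the dimmest 40% of probe sets, which does not decide it. That filter could move the share little, because 5815 of the 6486 reported calls were called in the same direction with it. A broad loss of transcripts in AtGATA2ox stays open as the biological explanation, untested.

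The changes of AtGATA2ox and bri1-116 in the same direction, with 1701 of 2045 shared calls alike, may come in part from the shared Col arrays. With the genotypes set against different Col arrays the covariance of the fold changes was still 0.246 to 0.344 (0.455 with shared ones), which argues against the shared arrays as the only source. A stronger 3′ bias of the RNA in both genotypes than in Col could contribute and stays open. Across the 1701 probe sets, r between the slope on the actin 3′ to 5′ ratio within groups and the fold change was 0.15, between the 5th and 95th percentiles (-0.19 and 0.22) of 100 permutations of the ratio. A response that the genotypes share is a candidate explanation that stays open too, as is any growth difference between seedlings of these genotypes, which was not measured here.

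In fits of the 6 arrays of each comparison alone, 1 of the 10 splits, the real one, gave as many calls: 5507 for AtGATA2ox against Col, 5182 for bri1-116 against Col and 4965 for AtGATA2ox against bri1-116, and the highest of the other splits gave 0 in each. With 10 splits the share cannot fall under 0.05.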

How the results depend on the processing

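Scaling to the hybridisation controls and leaving out bri1-116 replicates 1 and 2 together were chosen after the data were seen, and the other settings were planned. In each pair or trio of counts the order is higher, lower and, for calls in both genotypes, opposite.

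Of the counts and covariances under all settings except those that leave out 1 array each, 124 stayed within 1.5 times the reported value or its spread and 62 did not. Of the list results 1324 kept their direction and their side of the threshold, 28 gained and 48 lost a call, and 1 reversed. Of the named genes' results 1134 kept both, 4 gained and 19 lost a call, and 7 moved.

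AtGATA2ox against Col (2211 and 4275) had 3465 and 2501 with centring on the median and 421 and 11909 with scaling to the hybridisation controls. It had 1269 higher at 2-fold or more, 1419 and 2675 at adjusted p under 0.01, and 1107 and 2176 with 1 probe set per locus, where 13355 were tested. Centring on the median gave 990 higher and 659 lower in both genotypes (643, 1058 and 344 reported).

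For bri1-116 against Col (1612 and 1819) the counts were 976 and 1128 with eBayes without a trend, 814 and 1181 at 2-fold or more, 970 and 1050 at adjusted p under 0.01, 832 and 856 with 1 probe set per locus, and 482 and 3381 with scaling to the hybridisation controls. With replicate 3 as the only bri1-116 array, assumed to vary like the other groups, they were 571 and 845. The lower count was 2776 with only the arrays of the 2 groups compared and 2751 with array weights.

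The direct comparison (2172 and 3914) gave 1416 and 2553 at 2-fold or more, 2437 lower at adjusted p under 0.01, 1070 and 2104 with 1 probe set per locus, 912 and 7754 with scaling to the hybridisation controls, and 1071 and 1207 with the single bri1-116 array.

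Calls in both genotypes were 374, 659 and 113 without a trend, 263, 636 and 100 at 2-fold or more, 367, 587 and 122 at adjusted p under 0.01, and 294, 485 and 164 with 1 probe set per locus. They were 984, 1639 and 691 with an unadjusted p under 0.05 in the other comparison, 93, 2797 and 219 with scaling to the hybridisation controls, and 312, 529 and 88 with the single bri1-116 array. With array weights 519 were opposite.

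Of the fixed lists 3, 6 and 3 were called for AtGATA2ox, bri1-116 and the direct comparison, and 0 in each with an estimated correlation. Fry called 6 for AtGATA2ox and 6 for the direct comparison, and 1 was called there without the dimmest 40% of probe sets. Of the lists added later 5, 5 and 3 were called, and 0 in each with an estimated correlation. For AtGATA2ox these were 10 with fry, 3 without the dimmest 40% of probe sets and 2 with scaling to the hybridisation controls, and fry called 5 in the direct comparison. The plastid-encoded list reversed to a median of -0.294 in bri1-116 with the single array. A stricter threshold lowers a count by construction, and leaving 1 array in a group raises the SE by construction, which tends to lower counts too. For the other changes the cause was not tested.

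With each array left out in turn, AtGATA2ox had 1725 to 2269 higher and 3069 to 4456 lower, bri1-116 had 1055 to 1900 and 1097 to 2215, and the direct comparison 1775 to 2173 and 2807 to 4227. Both genotypes had 416 to 749 higher, 626 to 1250 lower and 162 to 454 opposite. The lowest bri1-116 and shared counts came without Col replicate 2. Opposite calls were also few without bri1-116 replicates 1 (200) or 2 (204) and Col replicates 1 (206) or 3 (171). The covariance difference was 0.203 to 0.269, r 0.397 to 0.47, and the called fixed lists 2 to 5, 5 to 7 and 3 to 3, with 5 for AtGATA2ox without its replicate 3. The called lists added later were 3 to 6, 5 to 8 and 2 to 3, with 3 for AtGATA2ox without Col replicate 2 and 8 for bri1-116 without Col replicate 3.

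The replicate number as a block gave 2204 and 4256, 1584 and 1855, 2147 and 3889, and 659, 1085 and 360. Residual correlations of arrays with the same number were -0.04 to 0.088 and of others -0.095 to 0.123. Between bri1-116 and AtGATA2ox those with the same number were 0.036 to 0.088 and the others -0.075 to 0.01. Between bri1-116 and Col they were 0.007 to 0.016 and the others -0.011 to -0.001. Between Col and AtGATA2ox the ranges overlapped (-0.04 to 0.078 and -0.095 to 0.123). A weak pairing of the arrays by number is therefore not excluded. A floor at the 20th percentile was not run, because at most 3 probe sets of an array shared its lowest value. Without detection calls, signal over background was not assessed for each probe set. In simulated data 22.1% of changes of 1 on the log2 scale were found for AtGATA2ox. Those data held 200 changed probe sets per genotype, far fewer than were called here, so the share does not carry over.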

Other observations

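No test in this part was chosen after its result was seen, except the scaling to the hybridisation controls and the fit with replicate 3 as the only bri1-116 array; the families were defined by symbol after the annotation was read and before any test.

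The sugar transporter gene SWEET3 fell in both genotypes, with log2 fold changes of -3.43 ± 0.32 in AtGATA2ox and -3.44 ± 0.32 in bri1-116 (n = 3 per group), and SWEET2 rose in AtGATA2ox (2.74 ± 0.32) and fell in bri1-116 (-1.34 ± 0.32), with a direct difference of 4.09. SWEET11 (-1.6 and -0.9) and SWEET17 (-1.99 and -1.57) fell in both. The family list was not called, with 1 higher and 3 lower of 14 in AtGATA2ox (adjusted p = 0.82), 5 lower in bri1-116 (0.085), and 2 higher and 1 lower between the genotypes (0.28). In bri1-116 the list passed without the dimmest 40% of probe sets (0.019), without bri1-116 replicate 1 (0.034) and without Col replicate 3 (0.033).

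In the TBL family, whose named members include enzymes that acetylate wall polymers, TBL38 fell 14.8-fold in AtGATA2ox and 4.79-fold in bri1-116, and TBL37 fell 5.93-fold and 3.71-fold. TBL36 fell in AtGATA2ox (-2.34 ± 0.21) and rose in bri1-116 (0.85 ± 0.21; 0.4 and not called with scaling to the hybridisation controls). The family was 1 higher and 4 lower of 22 in AtGATA2ox (median -0.51, adjusted p = 0.042, and adjusted p = 0.67 with an estimated correlation), 1 higher and 5 lower in bri1-116 (0.062), and 3 higher and 7 lower between the genotypes (0.61). Its AtGATA2ox call was lost without Col replicate 2 (0.071) or AtGATA2ox replicate 1 (0.077), with quantile normalisation (0.064), without the dimmest 40% of probe sets (0.12), with the replicate block (0.054) and with scaling to the hybridisation controls (0.071). In bri1-116 the family passed without bri1-116 replicate 1 (0.023) or Col replicate 3 (0.026), and with replicate 3 as the only bri1-116 array (0.016). Endoglucanase genes of family GH9 had GH9C2 lower in both (3.54-fold and 8.55-fold) and GH9B8 lower in AtGATA2ox (7.26-fold). The GH9 list had 3 and 2 of 15 lower (adjusted p = 0.53 and 0.16; 0.42 between the genotypes).

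Among glycosyltransferase genes UGT88A1 rose in both (4.01-fold in AtGATA2ox and 3.39-fold in bri1-116), and UGT71C1 (10.9-fold and 9-fold) and UGT72E2 (10.3-fold and 2.54-fold) fell in both. The list had 7 higher and 9 lower of 47 in AtGATA2ox (adjusted p = 0.53), 2 and 6 in bri1-116 (0.69), and 7 and 7 between the genotypes (0.35). The glutathione transferase gene GSTU26 fell in both (4.26-fold and 5.85-fold), with 2 higher and 6 lower of 13 in AtGATA2ox (0.35), 1 lower in bri1-116 (0.31), and 2 and 3 between the genotypes (0.96). The beta-glucosidase gene BGLU44 fell in AtGATA2ox (-1.36 ± 0.25) and rose in bri1-116 (1.52 ± 0.25), with a direct difference of -2.88. Its family had 1 higher and 4 lower of 21, 3 and 2, and 2 and 1 in the 3 comparisons (0.74, 0.85 and 0.74). Cytochrome P450 genes of the CYP71B subfamily were 1 higher and 6 lower of 19 in AtGATA2ox (0.76), with none called in bri1-116 (1) and 1 and 3 between the genotypes (0.74).

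HIS1-3, a linker histone gene, fell 6.21-fold in AtGATA2ox and was, with HON4, the pair called among 7 histone genes (adjusted p = 0.36). BZIP60, of the unfolded protein response, rose 3.17-fold in AtGATA2ox (log2 0.61 and not called with scaling to the hybridisation controls), with 1 lower gene of 11 in the same list (0.55), none called in bri1-116 (0.38), and 2 higher between the genotypes (0.17). Of 10 autophagy genes ATG8H rose and ATG3 and ATG8G fell in AtGATA2ox, while the rise of ATG8E (0.92) was -0.13 with scaling to the hybridisation controls, where ATG8H was not called either (0.18). The list adjusted p was 0.76, 0.38 in bri1-116 (0.036 with scaling to those controls), where APG8A fell (not called with centring on the median), and 0.45 between the genotypes. Of 15 tetraspanin genes TET2 fell 5.13-fold and TET9 rose 5.47-fold in AtGATA2ox, with 2 higher and 2 lower (1), 1 and 4 in bri1-116 (0.098), and 4 and 2 between the genotypes (0.28). Late embryo and dehydration genes were 2 higher and 4 lower of 14 in AtGATA2ox (0.42), with DI21 2.73-fold higher (log2 0.4 and not called with scaling to the hybridisation controls), 2 and 1 in bri1-116 (0.67), and 1 and 4 between the genotypes (0.6).

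The auxin gene families had 2 higher and 2 lower of 17 in AtGATA2ox (adjusted p = 0.53), with YUC6 lower (-2.37; adjusted p = 0.052 with centring on the median), 3 and 2 in bri1-116 (0.72), with HAT2 lower (-2.11), and 3 and 3 between the genotypes (0.68). Of 18 mitosis genes AUR1 fell in both genotypes against Col, and the rise of FBL17 in AtGATA2ox (0.95) was -0.1 with scaling to the hybridisation controls (list adjusted p = 0.85, 0.36 and 0.55). Of 10 plastid-encoded NDH genes ndhA fell in AtGATA2ox (-2.07), and the rises of ndhC and ndhD (0.43 and 0.63) were -0.62 and -0.42 with scaling to the hybridisation controls. The NDH list adjusted p was 0.75, 0.42 in bri1-116 with none called (0.034 without bri1-116 replicate 3), and 0.76 between the genotypes with 2 lower. Of 19 plastid-encoded expression genes none was called against Col (0.53 and 1), and 2 were lower in AtGATA2ox than in bri1-116 (0.55). With scaling to the hybridisation controls 17 were lower in AtGATA2ox than in Col (median -1.31), and with centring on the median 2 were higher in bri1-116 than in Col.

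With scaling to the hybridisation controls the counts of higher and lower members in AtGATA2ox became 1 and 18 for glycosyltransferases, 0 and 6 for glutathione transferases, 0 and 6 for beta-glucosidases, 0 and 7 for CYP71B genes, 0 and 16 for TBL genes, 0 and 7 for GH9 genes, 1 and 8 for tetraspanins and 0 and 9 for late embryo genes. They were 0 and 6 for histones, 0 and 9 for the unfolded protein response, 0 and 8 for autophagy, 0 and 10 for mitosis, 0 and 6 for NDH genes and 1 and 8 for the auxin families. In bri1-116 that scaling gave 1 and 10 for glycosyltransferases, 1 and 5 for beta-glucosidases, 0 and 6 for TBL, 0 and 4 for GH9, 0 and 5 for tetraspanin, 1 and 2 for late embryo, 0 and 4 for autophagy and 1 and 4 for auxin genes. Between the genotypes it gave 3 and 13 for glycosyltransferases, 0 and 5 for beta-glucosidases, 1 and 6 for CYP71B, 1 and 9 for TBL, 2 and 2 for tetraspanin, 1 and 5 for autophagy and 3 and 5 for auxin genes. Centring on the median gave 9 and 5 for glycosyltransferases, 1 and 2 for CYP71B, 2 and 3 for beta-glucosidases, 2 and 2 for late embryo and 1 and 0 for mitosis genes in AtGATA2ox.

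With fry the GH9 (0.033), late embryo (0.005), histone (0.0063) and glutathione transferase (0.011) lists passed in AtGATA2ox, the GH9 list in bri1-116 (0.03), and the late embryo list between the genotypes (0.026).

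The 5S ribosomal RNA probe set read 102 ± 42.7 in AtGATA2ox, 21 in Col and 10.7 in bri1-116, and the 25S probe set lay between 110.4 and 502.8 on the AtGATA2ox arrays.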
